A study of Mus musculus with 18 samples.

How the data were processed

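Bulk RNA sequencing was done on 18 libraries of cultured mouse cortical astrocytes, 3 libraries in each of 6 groups. Per the labels' protocols the cells carried a plasmid for a designer receptor (DREADD) or for a fluorescent control protein, received 8 µM of the ligand deschloroclozapine (DCZ) for 90 min, 7 days after transfection, and were lysed at 90 min or after 3 further days in medium without ligand. Messenger RNA was enriched by its poly-A tail, per the labels' protocols. The submitters' processing notes name fastp 0.23.4, Salmon 1.8.0 and the mm39 build, with no role or order. The deposited values are estimated counts per gene, not normalised, in a table of 12 libraries at 90 min and a table of 6 libraries at 3 days. Of the values 55.9% at 90 min and 30.5% at 3 days were not whole numbers. Both tables hold the same 22078 Entrez gene identifiers in the same order. How transcripts were summed to genes is not stated, nor whether counting used strand, so near-identical paralogs, overlapping genes and antisense pairs are uncertain.

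The estimated counts were rounded to whole numbers before testing. Symbols were taken from a reference gene table by Entrez identifier. It matched 21978 identifiers, or 99.55%, and the rest held 0.034% of the counts. The files use mm39 and the reference annotation is of GRCm38, so no coordinates are given. Chrm4, Mmp3 and the transcripts of the mitochondrial genome are not analysed here.

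The test of each comparison was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust dispersion, TMM normalisation and edgeR's default filter on low counts. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. The 4 groups at 90 min were fitted together over 12 libraries with 8 residual degrees of freedom, so that they share 1 estimate of the spread. The 3-day groups were fitted over 6 libraries with 4 residual degrees of freedom. The difference between times was an interaction contrast over the 12 libraries of hM3Dq and its control at both times, each effect taken against its own control. These fits, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Alternatives chosen after seeing the data are named as such where they appear.

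Gene lists were 26, of which 20 hold response genes and 6 hold markers of other cell types or of RNA quality. They share some genes, so their results are not independent. They held 559 genes, of which 545 are in the tables. Lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), which compares a list's members with all other genes tested. This gave 24 lists at 90 min and 23 at 3 days, adjusted over the lists within each comparison. Camera with a correlation estimated from the residuals, and fry, which tests whether a list's own genes move on balance in 1 direction and does not compare them with other genes, were alternatives. List counts are given over all genes tested and adjusted over the list alone.

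The genes named for each comparison against a control were Fos, Egr1, Nr4a1, Chrm3, Chrm4 and Gfap, the 6 called genes with the highest and the 6 with the lowest fold change among genes with a mean log2 CPM of at least 1 and groups that do not overlap, the 2 called members with the smallest p of each list with at least 3 called members, and the 5 smallest p where fewer than 10 genes were called. For comparisons between receptors and between times the 5 highest and 5 lowest called genes were named. Any other named gene was chosen after its values were seen. Identifiers are given in brackets as Entrez numbers for the genes described first.

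The tests of the 3 receptors against EGFP, of hM3Dq at 3 days and of the difference between times were tried on simulated counts. These counts were drawn from the real means and library sizes, with 200 genes changed. The tests between receptors were not simulated. At a 2-fold change the test recovered 71% of changed genes for hM3Dq, 69% for rM3Ds, 65% for hM4Di, 88% for hM3Dq at 3 days and 60% for the difference between times. At a 4-fold change it recovered 89%, 88%, 90%, 99% and 95% in the same order. False calls were 8 of 168 calls, 11 of 168, 9 of 164, 14 of 201 and 6 of 161 in that order. The simulations ran on 13584 genes at 90 min, 12807 at 3 days and 13391 for the difference. Each gene was drawn on its own, so they hold no shift shared by many genes, such as that of the libraries that stand apart. The shares recovered therefore do not tell how many changes the real fits missed.

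Library totals were 16.1 to 25.2 M counts at 90 min and 16.6 to 19.7 M at 3 days. A floor of 3 counts in a library corresponded to 0.119 to 0.187 CPM. Floors cover counting error only. The labels number replicates 1 to 3 but do not say that these are separate cultures, so the p-values measure the spread between libraries, which may be partly technical. Whether the numbers pair libraries was checked from the correlation of same-numbered libraries' deviations from their group means. For hM3Dq and EGFP at 90 min every pair passed the limit of 0.1 set for pairing, with r of 0.133, 0.162 and 0.123 across genes, which are not independent replicates. That comparison is therefore also given with the replicate number as a block. For the other comparisons not every pair passed. Same-numbered r was -0.764, -0.573 and -0.566 for rM3Ds and EGFP, and 0.373, 0.098 and 0.305 for hM4Di and EGFP. The check therefore does not show that the numbers mark shared cultures.

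Alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors in place of TMM, no filter and a stricter filter on low counts (10 counts and 1 CPM in 3 libraries), only the groups compared, the replicate block, each library left out in turn, and, chosen after seeing the data, the removal of or a term for libraries that stand apart, the replicate block with only hM3Dq and EGFP fitted, and offsets for GC content and transcript length. GC content and length came from the longest annotated transcript of each gene and were known for 98.4% of the genes tested at 90 min and 98.5% at 3 days. Overlaps of comparisons that share the EGFP libraries were set beside 50 simulations of unchanged groups. Plots were made with matplotlib 3.10.9 in Python 3.11.15.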

Results

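Gene expression was measured by RNA sequencing in cultured cortical astrocytes from mouse brain after stimulation of 1 of 3 designer receptors (DREADDs). These are muscarinic receptors changed so that they respond to a synthetic ligand, here DCZ. The receptor hM3Dq is built on the human M3 receptor and couples to Gq, which raises intracellular calcium. The receptor rM3Ds is built on the rat M3 receptor and couples to Gs, which raises cAMP, and hM4Di is built on the human M4 receptor and couples to Gi, which lowers cAMP. Cells with each receptor, and control cells with EGFP, received 8 µM DCZ for 90 min. Cells with hM3Dq, and control cells with mCherry, were also taken 3 days after the same stimulation. The control cells received DCZ too, so the comparisons separate the receptor from effects of the ligand alone. No group carried a receptor without DCZ, so stimulation cannot be told apart from other effects of carrying the receptor. Each of the 6 groups had 3 libraries. Total counts were 18.2 to 25.2 M for hM4Di, 16.6 to 20.1 M for hM3Dq, 16.1 to 17.7 M for rM3Ds and 17.2 to 21.5 M for EGFP at 90 min. At 3 days they were 17.2 to 19.7 M for hM3Dq and 16.6 to 18.5 M for mCherry. Levels below are mean CPM ± SD over the 3 libraries of a group, log2 fold changes are given ± SE, and adjusted p-values for genes are from edgeR unless another tool is named.

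At 90 min 3 libraries stood apart from the other 9. These were EGFP 1, rM3Ds 2 and rM3Ds 3, and they separated on a principal component that held 52.5% of the variance. The cell cycle genes moved with them: the median over the list's 32 members, relative to each gene's mean over the 12 libraries, was 2.00 in EGFP 1, 1.29 in rM3Ds 2 and 1.24 in rM3Ds 3, against -0.84 in rM3Ds 1, -0.66 in EGFP 2 and -0.94 in EGFP 3 (log2). In these libraries Mki67, a proliferation marker, lay 3.66 higher on the log2 scale than in the other libraries of their groups, and Fabp7, a marker of glial progenitors, lay 4.22 higher. The complement gene C3 lay at -3.53 and Steap4, a metalloreductase of inflammation, at -3.25 by the same measure. At 3 days mCherry 3 stood apart on a component that held 56.7% of the variance.

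After 90 min of DCZ the immediate-early genes, the transcription factors and regulators that activity induces within minutes, were higher with hM3Dq than with EGFP. Fos (Entrez 14281) rose from 13.4 ± 2.94 CPM with EGFP to 54.0 ± 1.78 CPM with hM3Dq (n = 3 per group), a log2 fold change of 2.01 ± 0.16 (adjusted p = 6.18e-05). Fosb (14282) rose by 3.57 ± 0.33 and Fosl1 (14283), another AP-1 subunit, by 3.39 ± 0.16, from 3.93 ± 0.65 to 41.6 ± 4.99 CPM (adjusted p = 3.51e-06). The orphan nuclear receptors Nr4a1 (15370), Nr4a2 (18227) and Nr4a3 (18124) rose by 2.00 ± 0.15, 3.21 ± 0.18 and 3.32 ± 0.37, and Nr4a1 reached 467 ± 33.8 CPM. The stress-inducible factor Atf3 (11910) rose by 2.82 ± 0.15. Egr4 (13656) had the highest fold change of the genes named by rule, at 4.08 ± 0.56, though with EGFP it lay near the floor of 3 counts, so that this fold is uncertain, and Egr1 (13653) rose by 2.40 ± 0.42 (adjusted p = 0.0269). Of the list's 32 tested members 18 rose over all genes tested, none fell and 14 did not pass, and 29 rose when adjusted over the list alone. The list's median log2 fold change was 1.32, and it lay above the other genes (limma camera adjusted p = 1.73e-58, and adjusted p = 0.000585 with an estimated correlation).

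**Figure D1:**
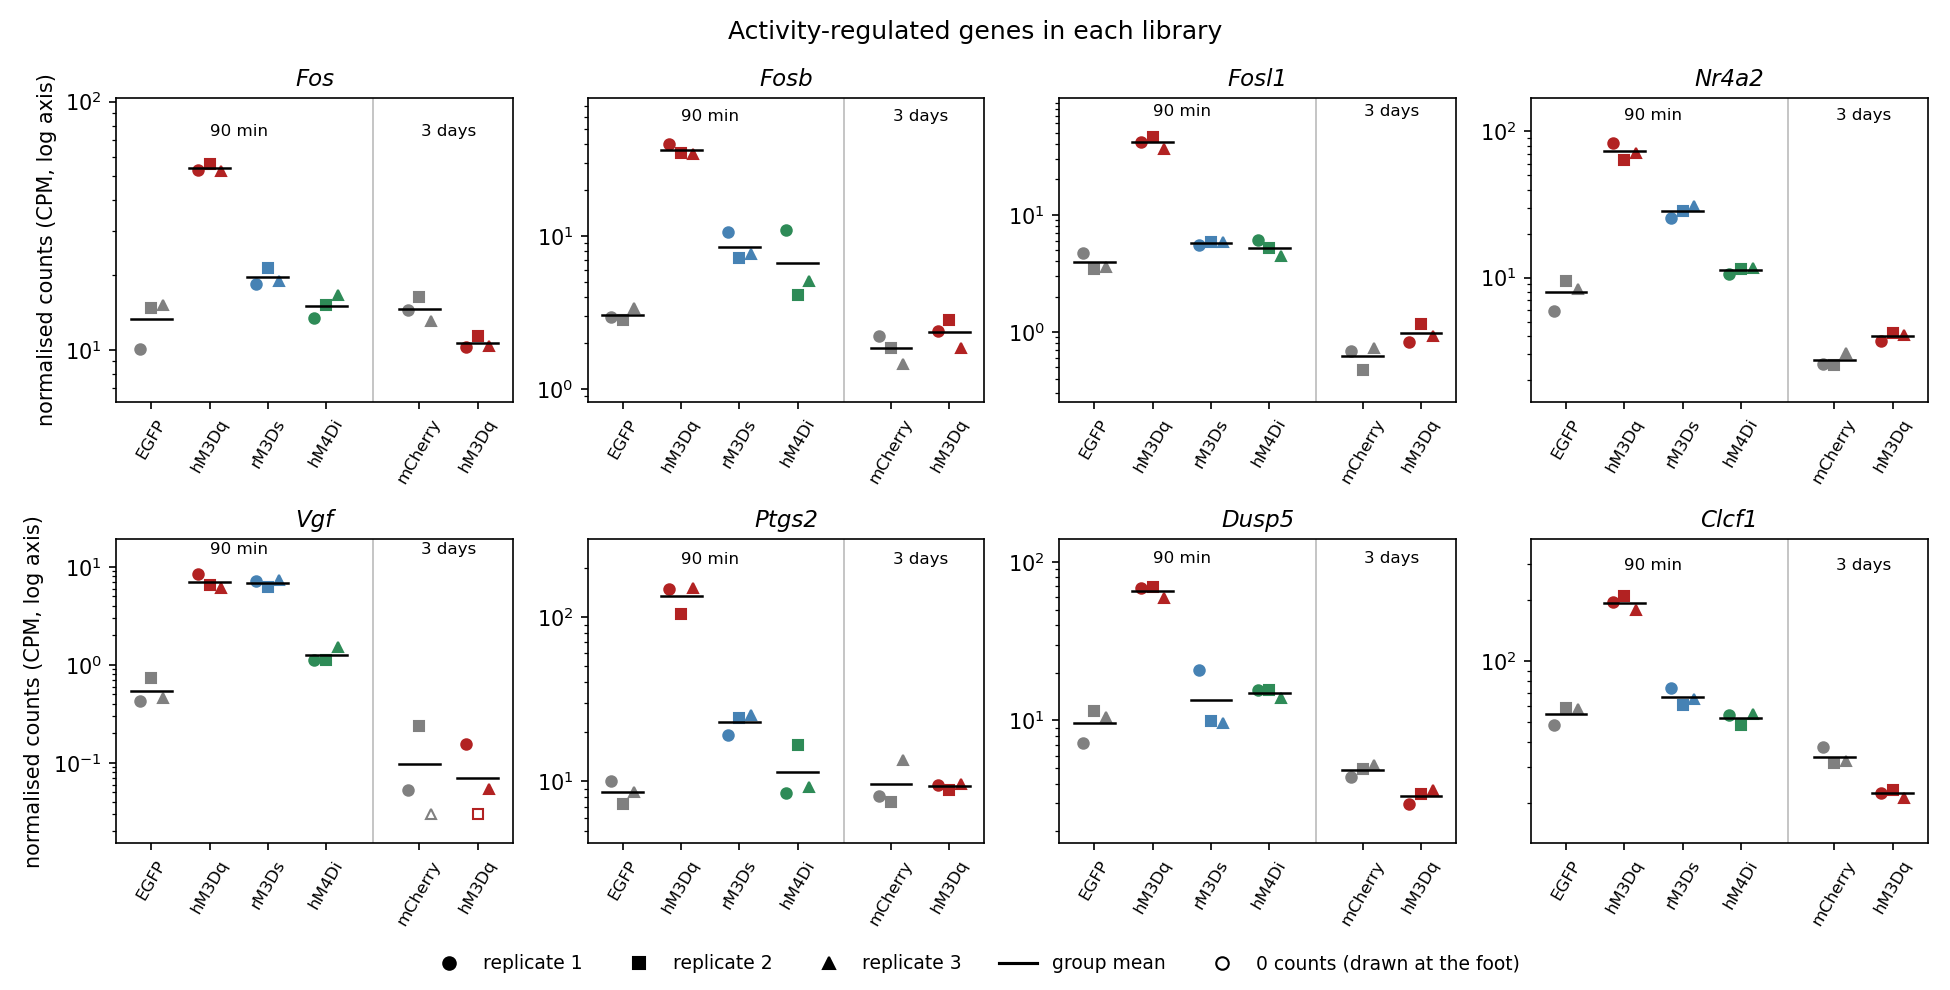
Normalised counts (CPM, log axis) of 8 genes in each of the 18 libraries, by group, with the group mean as a bar; open symbols at the foot mark 0 counts. Fos lies at a mean of 54.0 CPM with hM3Dq and 13.4 CPM with EGFP at 90 min, and Vgf lies at 7.08 CPM with hM3Dq and 6.89 CPM with rM3Ds against 0.54 CPM with EGFP.

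Signalling genes downstream of calcium and of growth factor pathways rose with hM3Dq. Ptgs2 (19225), the inducible cyclooxygenase that starts prostaglandin synthesis, rose from 8.66 ± 1.25 to 135 ± 25.8 CPM, a log2 fold change of 3.96 ± 0.27. Nfatc2 (18019), a transcription factor activated by calcineurin, rose by 2.61 ± 0.35. Of the 12 tested calcineurin-NFAT responsive genes 4 rose, none fell and 8 did not pass, with 7 higher when adjusted over the list alone (camera adjusted p = 6.67e-09, and 0.0017 with an estimated correlation). The phosphatases Dusp5 (240672) and Dusp10 (63953), which switch off MAP kinases, rose by 2.77 ± 0.28 and 1.44 ± 0.14. Of 20 ERK feedback genes 6 rose, none fell and 14 did not pass, with 7 higher when adjusted over the list alone (camera adjusted p = 8.84e-09, and 0.00551 with an estimated correlation). Vgf (381677), a secreted neuropeptide precursor induced by cAMP and growth factors, rose by 3.69 ± 0.27 from a low level of 0.54 CPM with EGFP. Of 25 tested cAMP-CREB responsive genes 6 rose, none fell and 19 did not pass, and 12 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 2.49e-14, and 0.00551 with an estimated correlation).

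Genes of secreted factors rose as well. Clcf1 (56708), a cytokine of the CNTF family, rose from 55.3 ± 6.21 to 195 ± 15.2 CPM, by 1.82 ± 0.11, and Inhba (16323), the activin A subunit, rose by 1.46 ± 0.19. Among growth and neurotrophic factors 7 of 32 tested members rose, none fell and 25 did not pass. Others that rose included Lif, Hbegf, Gdnf and Pdgfa, chosen after their values were seen, at 1.67, 0.99, 2.19 and 0.51. Adjusted over the list alone 9 were higher, and camera gave adjusted p = 1.92e-09, and 0.00111 with an estimated correlation. Of 19 tested inflammatory and NF-kB responsive genes 2 rose, Ptgs2 and the chemokine Cxcl2 at 6.04 ± 0.85, none fell and 17 did not pass. Cxcl2 missed the rule's limit of a mean log2 CPM of at least 1 or that of groups without overlap, so its fold is uncertain. Adjusted over the list alone 9 were higher (median 0.71, camera adjusted p = 6.28e-15, and 0.014 with an estimated correlation). Of 35 tested reactive astrocyte genes 4 rose, Clcf1, Ptgs2, Ptx3 and Cd14, and 31 did not pass (median 0.21, camera adjusted p = 6.97e-05, and 0.00551 with an estimated correlation), with 4 higher when adjusted over the list alone.

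The called genes that were lower with hM3Dq moved less, and with the replicate number as a block they lost their calls (adjusted p = 0.0524 to 0.102). Gpr146 (80290), an orphan receptor gene, fell by 0.81 on the log2 scale (SE 0.16), Mtss1 (211401), which binds actin at membranes, fell by 0.76 (SE 0.13), Mmp11 (17385), a matrix metalloproteinase, fell by 0.63 (SE 0.11) and Pik3ip1 (216505), an inhibitor of PI3-kinase, fell by 0.56 (SE 0.09). Gfap, the astrocyte intermediate filament gene, was at 2.53 ± 0.26 CPM with hM3Dq and 9.18 ± 12.1 CPM with EGFP (log2 fold change -1.86 ± 1.01, adjusted p = 0.722), and without EGFP 1 the estimate was 0.21. It was low in the other groups too, at 7.87 CPM with rM3Ds and 7.22 CPM with hM4Di. At 3 days it was at 3.27 CPM with hM3Dq and 2.04 CPM with mCherry. That the cells were astrocytes is taken from the labels and was not tested. Chrm3 was at 10.8 ± 1.34 and 6.06 ± 4.15 CPM (0.85 ± 0.53, adjusted p = 0.779). Reads of the transfected receptor can be assigned to the mouse gene in part at most, so this value does not check the label.

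In the same comparison further lists passed camera with the preset correlation only. Unfolded protein and integrated stress response genes had a median of 0.20, with 2 of 23 higher over all genes, Chac1 and Ddit3, and 6 when adjusted over the list alone (camera adjusted p = 6.49e-08; adjusted p = 0.0739 with an estimated correlation). Glycolysis, glycogen and lactate transport genes had a median of 0.12, with 2 of 26 higher, Pdk4 and Hk2, by either adjustment (0.00232; adjusted p = 0.0959 with an estimated correlation). Heat shock genes had a median of 0.16, with 1 of 14 higher and 2 when adjusted over the list alone (0.00546; adjusted p = 0.076 with an estimated correlation). Extracellular matrix and protease genes had a median of 0.05, with 2 of 29 higher, among them Adamts1, and 3 when adjusted over the list alone (0.0142; adjusted p = 0.329 with an estimated correlation). Cholesterol synthesis genes had a median of 0.09 with no member called among 24 (0.02; adjusted p = 0.699 with an estimated correlation). Heat shock genes lost the camera call without EGFP 2 or EGFP 3 (adjusted p = 0.0884 and 0.0612). Matrix genes lost it without hM3Dq 1, EGFP 2 or EGFP 3 (medians of -0.04, 0.03 and -0.01, 0.0727, 0.113 and 0.281), and so did cholesterol genes (0.0688, 0.191 and 0.219). The 32 cell cycle genes had a median of -1.40 with no member called by edgeR (camera adjusted p = 0.000127; adjusted p = 0.699 with an estimated correlation), but their median was 0.22 without EGFP 1, the control library with the high cell cycle level given above. The other 11 lists tested had camera adjusted p from 0.0703 for synapse-regulating factors to 0.879 for circadian clock genes. Among these the median and mean differed in sign for synapse-regulating factors (0.09 and -0.05), homeostatic astrocyte genes (0.14 and -0.14), endothelial markers (0.08 and -0.10) and SRF-MRTF and YAP targets (-0.01 and 0.02). The marker lists of neurons, oligodendrocytes, fibroblasts and mural cells and endothelium had adjusted p of 0.56, 0.66, 0.637 and 0.494, and 3 microglia markers had a median of -0.28 with no test.

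For hM3Dq against EGFP at 90 min edgeR tested 13584 genes and called 107, of which 103 were higher and 4 lower, with 59 higher at least 2-fold. With the replicate number as a block it called 66 genes, all higher, and 65 of these were among the 107. DESeq2 called 232, including all 107. The count was 51, 52 and 60 without hM3Dq 1, 2 or 3, and 50 and 59 without EGFP 2 or 3. Without the 3 libraries that stand apart, an alternative chosen after seeing the data, it was 143, of which 88 were among the 107. Egr1 and the 4 lower genes each lost the call without at least 4 single libraries, at adjusted p from 0.0515 to 0.206, and the 4 lower genes lost it under the block at 0.0524 to 0.102. With only hM3Dq and EGFP fitted and the block, an alternative also chosen after seeing the data, 28 genes were called, and Egr1, Vgf, Nr4a3, Nfatc2 and Inhba lost the call as well (0.113, 0.0553, 0.143, 0.108 and 0.105).

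After 90 min of DCZ Vgf and Nr4a2 were higher with rM3Ds than with EGFP. Vgf rose from 0.54 ± 0.17 CPM with EGFP to 6.89 ± 0.59 CPM with rM3Ds (n = 3 per group), a log2 fold change of 3.66 ± 0.27 (adjusted p = 0.000458). Its level with EGFP was low, at 0.431 to 0.738 CPM per library, so the size of this fold is less certain. With single libraries left out the fold was 3.51 to 3.95. Nr4a2 rose from 7.95 ± 1.92 to 28.4 ± 2.64 CPM, by 1.84 ± 0.17 (adjusted p = 0.00203). Both are targets of the cAMP-activated factor CREB. The next genes by p did not pass: Enc1, an actin-binding protein of neural cells, at 0.88 ± 0.13 (adjusted p = 0.117), Crem, a cAMP-responsive transcription factor, at 0.59 ± 0.09 (0.195), and the chemokine Cxcl1 at 2.39 ± 0.40 (0.2). Fos was at 19.6 ± 1.51 CPM (0.55 ± 0.15, adjusted p = 0.621), Egr1 at 0.11 ± 0.42 and Nr4a1 at 0.42 ± 0.15, none of which passed, and the Egr1 estimate was -0.05 and -0.13 without EGFP 2 or EGFP 3. Gfap was at -0.23 ± 0.95 and Chrm3 at 1.17 ± 0.54 (adjusted p = 1.00 for both), and the Gfap estimate was 1.86 without EGFP 1 and 0.10 without rM3Ds 1.

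Among lists in the rM3Ds comparison, cAMP-CREB responsive genes had 2 of 25 members higher over all genes and 9 when adjusted over the list alone, with a median of 0.38 (camera adjusted p = 3.93e-19, and 0.00811 with an estimated correlation). Besides Vgf, Nr4a2 and Crem, the values included Rgs2, which limits G protein signalling, at 1.17 ± 0.20 and Dio2, the deiodinase that activates thyroid hormone, at 1.42 ± 0.32, neither called over all genes. Immediate-early genes had 1 of 32 higher over all genes and 12 adjusted over the list alone (median 0.41, camera adjusted p = 1.52e-17, and 0.0194 with an estimated correlation). The growth factor, reactive astrocyte, calcineurin-NFAT and ERK feedback lists had no member called over all genes, with 2, 2, 3 and 2 higher when adjusted over the list alone. Camera placed them above other genes (adjusted p = 0.00171, 0.0035, 0.0035 and 0.00015, and 0.0342, 0.0388, 0.0418 and 0.0418 with an estimated correlation). Without rM3Ds 1 the NFAT and reactive lists were at 0.0688 and 0.068, and without EGFP 1 the reactive list was at 0.0992. Inflammatory genes had a median of 0.17 and 5 of 19 higher when adjusted over the list alone, among them Cxcl5 at 3.36 ± 0.59 (camera adjusted p = 9.87e-06; adjusted p = 0.119 with an estimated correlation), and lost the call without rM3Ds 1 or EGFP 1 (medians of -0.02 and 0.01, 0.0842 and 0.178).

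Lists that passed only with the preset correlation in the rM3Ds comparison were homeostatic astrocyte genes (median 0.18, adjusted p = 0.000818), glycolysis genes (0.12, 0.000818), synapse-regulating factors (0.16, 0.0035), TGF-beta, BMP and Notch targets (0.17, 0.00593) and cell cycle genes (0.04, 0.0306). Interferon-stimulated genes were lower (median -0.25, 0.000567). With an estimated correlation their adjusted p = 0.0604, 0.0779, 0.158, 0.177, 0.745 and 0.496 in that order. The homeostatic and glycolysis lists lost the camera call without EGFP 1 (0.0992 and 0.139), the synapse list without rM3Ds 3 (0.0867) or the 3 libraries that stand apart (median -0.03, 0.501), the interferon list without these 3 (median -0.15, 0.193) and the TGF-beta list without EGFP 2 (0.0742). The cell cycle list, which is high in rM3Ds 2, rM3Ds 3 and EGFP 1, had a median of -0.22 and -0.17 without rM3Ds 2 or 3, of -0.34 and -0.37 without EGFP 2 or 3 and of 1.75 without EGFP 1 (1.49e-11). With a term for the 3 libraries that stand apart it was lower and passed (-0.42, 1.84e-06). The other 11 lists tested had adjusted p from 0.0694 to 0.927.

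For rM3Ds against EGFP edgeR called 2 of 13584 genes, both higher, and 407 higher and 168 lower genes had an unadjusted p under 0.05. DESeq2 called 56 and limma-voom 2. Without rM3Ds 1, which leaves only rM3Ds libraries that stand apart, edgeR called 115. Without the 3 libraries that stand apart, which leaves a single rM3Ds library assumed to vary like the other groups, it called 0, with Vgf at 3.55 (adjusted p = 0.0539) and Nr4a2 at an adjusted p of 0.084. With only rM3Ds and EGFP fitted it also called 0, with the folds of Vgf and Nr4a2 at 3.66 and 1.84 and adjusted p of 0.183 and 0.339.

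**Figure D2:**
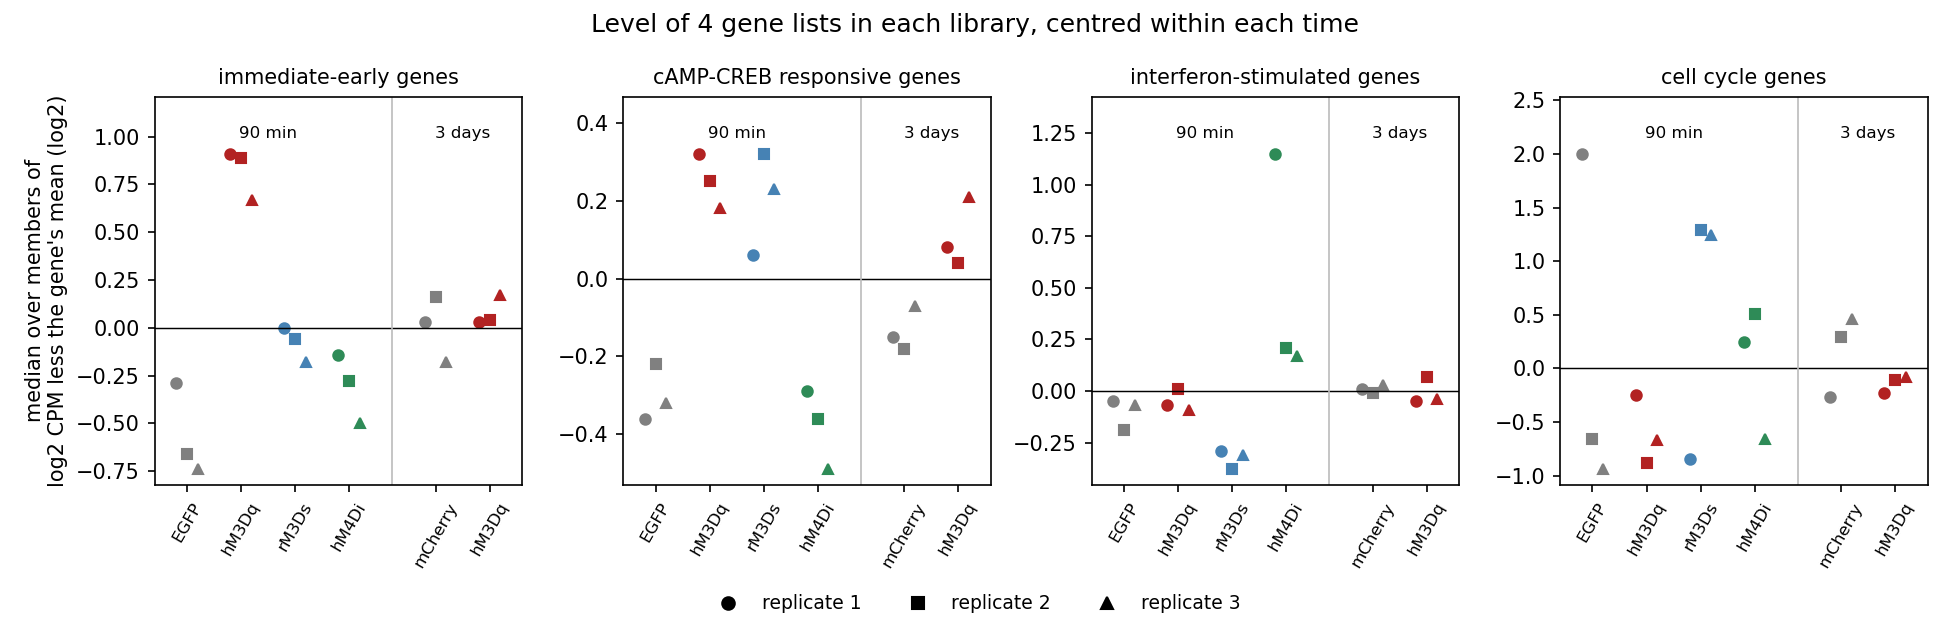
Level of 4 gene lists in each of the 18 libraries, as the median over list members of log2 CPM less each gene's mean over the libraries of the same time (log2). The interferon list lies at 1.15 in hM4Di 1 and the cell cycle list at 2.00 in EGFP 1.

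Stimulation of hM4Di for 90 min gave no called gene against EGFP (n = 3 per group). Interferon-stimulated genes were the list with the smallest camera p: 25 of 26 tested members had a log2 fold change above 0, with a median of 0.71. Bst2, which tethers enveloped viruses, was at 0.68 ± 0.14, Irf7, a transcription factor of the interferon response, at 1.10 ± 0.29 and Ifit3, an interferon-induced antiviral gene, at 0.88 ± 0.24. No member was called over all genes, 18 were higher when adjusted over the list alone, and camera gave adjusted p = 1.01e-17 (adjusted p = 0.235 with an estimated correlation). The list's level was 1.15 in hM4Di 1, 0.21 in hM4Di 2 and 0.17 in hM4Di 3, and without hM4Di 1 the median was 0.28 (camera adjusted p = 2.51e-08). Cholesterol synthesis genes had a median of -0.22, with Lss, lanosterol synthase, at -0.52 ± 0.18 (camera adjusted p = 5.15e-07; adjusted p = 0.465 with an estimated correlation). Without hM4Di 1 their median was -0.05 (0.639).

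The genes with the smallest p for hM4Di did not pass: Pak3, a kinase of the actin cytoskeleton, at -0.53 ± 0.09, Ifi35, an interferon-induced gene, at 0.57 ± 0.10 and Itga1, a collagen-binding integrin subunit, at -0.79 ± 0.14 (adjusted p = 0.515 for each), then Capg at 0.67 ± 0.13 and Ermp1 at -0.37 ± 0.08 (0.774 for both). Fos was at 15.1 ± 1.84 CPM (0.17 ± 0.15), Egr1 at 0.70 ± 0.41, Nr4a1 at 0.13 ± 0.15, Chrm3 at 0.17 ± 0.53 and Gfap at -0.35 ± 0.95, with adjusted p of at least 0.833. Without EGFP 1 the Chrm3 and Gfap estimates were -0.26 and 1.75, and Gfap was at 0.13 and 0.02 without hM4Di 2 or 3. Immediate-early genes had a median of 0.19 and inflammatory genes of 0.35 (camera adjusted p = 5.15e-07 and 3.09e-06; adjusted p = 0.235 for both with an estimated correlation). The cAMP-CREB list had a median of -0.03 and a mean of -0.30 although camera placed it above other genes without passing (0.169). Cell cycle genes had a median of -0.60 (0.855), and of 1.03 without the 3 libraries that stand apart (8.65e-14). Unfolded protein response genes had a median of 0.17, reactive astrocyte genes of 0.07 and matrix genes of -0.29 (0.0044, 0.00661 and 0.00383; adjusted p = 0.465, 0.17 and 0.399 with an estimated correlation). The stress list lost the call without hM4Di 3 (0.22), and the reactive and matrix lists without hM4Di 1 (0.0591 and 0.0827) or EGFP 1 (0.088 and 0.33).

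For hM4Di edgeR called 0 of 13584 genes, with 315 higher and 430 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.515. DESeq2 called 35, of which 21 were higher, and limma-voom 0. In this comparison 8.5% of genes had groups that did not overlap, against 10% by chance for 3 against 3. Genes are not independent replicates, so this share is no test.

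The receptors were also compared with each other, which tests the differences directly. Against rM3Ds, hM3Dq gave higher Nfatc2 (3.57 ± 0.37), Egr4 (3.02 ± 0.52), Fosl1 (2.86 ± 0.16), Npas4, an activity-dependent transcription factor (2.62 ± 0.42), and Ptgs2 (2.56 ± 0.25). Nfatc2, Egr4 and Npas4 were low with rM3Ds, at means of 0.52, 0.79 and 0.87 CPM, so the sizes of their folds are less certain. Cxcl5, a neutrophil chemokine, was lower than with rM3Ds by 3.17 (SE 0.58), and Gata2, Plekhg3, Arvcf and Id4 were lower by 1.44, 0.96, 0.92 and 0.92. Cxcl5 was at 2.13 CPM with hM3Dq, 1.88 CPM with EGFP and 19.4 CPM with rM3Ds, so its difference is a high level with rM3Ds. Of 32 immediate-early genes 13 were higher with hM3Dq, none were lower and 19 did not pass, and 25 were higher when adjusted over the list alone (camera adjusted p = 7.95e-26, and 0.0106 with an estimated correlation). The cAMP-CREB list had 4 members higher and 1 lower with a median of 0.04 and a mean of -0.09 (camera adjusted p = 0.342). The cell cycle list had a median of -1.47 (8.6e-06; adjusted p = 0.547 with an estimated correlation), and 0.27 without the 3 libraries that stand apart. In this comparison 10 lists passed camera and 1 with an estimated correlation. Of 13584 genes edgeR called 77 higher and 14 lower. The total of 91 was 463 with DESeq2 (260 higher, 203 lower) and 590 without rM3Ds 1 (278 higher, 312 lower), 28 and 33 without rM3Ds 2 or 3, and 31, 31 and 40 without hM3Dq 1, 2 or 3. Without the 3 libraries that stand apart it was 25, of which 20 were among the 91. Egr4, Npas4 and the 5 lower genes lost their calls without at least 4 single libraries each, all among these 5, at adjusted p of 0.0723 to 0.246, and without the 3 libraries that stand apart, where Gata2 was at -0.79 (adjusted p = 0.755). Nfatc2 also lost its call without these 3 libraries (3.18, adjusted p = 0.0714).

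Against hM4Di, hM3Dq gave higher Ptgs2 (3.56 ± 0.26), Fosl1 (2.99 ± 0.16), Nr4a3 (2.87 ± 0.36), Nr4a2 (2.71 ± 0.17) and Atf3 (2.50 ± 0.14). Plscr1, an interferon-inducible scramblase, was lower than with hM4Di by 0.59 (SE 0.09). The growth arrest gene Gadd45a, Nudt16, Pik3ip1 and the immunoproteasome subunit Psmb10 were lower by 0.59, 0.49, 0.48 and 0.45. Psmb10 was at 57.6 CPM with hM3Dq, 59.6 CPM with EGFP and 79.0 CPM with hM4Di, so its difference is a high level with hM4Di. Immediate-early genes had 14 of 32 higher and none lower, with 28 higher when adjusted over the list alone (camera adjusted p = 3.83e-37, and 0.00152 with an estimated correlation). Interferon-stimulated genes had a median of -0.60 with 15 of 26 lower when adjusted over the list alone and none over all genes (8.92e-11; adjusted p = 0.257 with an estimated correlation), where hM4Di 1 alone had the high level of 1.15 given above. In this comparison 12 lists passed camera and 5 with an estimated correlation. Of 13584 genes edgeR called 102 higher and 7 lower. The total of 109 was 38, 39 and 68 without hM3Dq 1, 2 or 3 and 60 and 40 without hM4Di 2 or 3. It was 300 without the 3 libraries that stand apart. None of these 3 is in either group compared, so that change came through what the fit shares across groups, such as the spread. Which part of the fit gave it was not tested. The 5 lower genes each lost the call without at least 1 of the 6 libraries compared, Plscr1 without hM3Dq 2 (adjusted p = 0.0554) and the others at 0.0555 to 0.211.

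Against hM4Di, rM3Ds gave higher Vgf (2.46 ± 0.25, adjusted p = 0.011) and Nr4a2 (1.34 ± 0.17, adjusted p = 0.0356), the 2 genes edgeR called of 13584, with 851 higher and 504 lower at an unadjusted p under 0.05. The cAMP-CREB list had 24 of 25 members above 0 with a median of 0.45 and 9 higher when adjusted over the list alone (camera adjusted p = 9.04e-11; adjusted p = 0.0554 with an estimated correlation). Interferon-stimulated genes had a median of -0.99 with 22 of 26 lower when adjusted over the list alone (1.59e-20; adjusted p = 0.139 with an estimated correlation), with the same high level of hM4Di 1. In all, 10 lists passed camera and 0 with an estimated correlation. DESeq2 called 205 genes. Without rM3Ds 1 edgeR called 392, without rM3Ds 2 or hM4Di 1 it called 1, and without rM3Ds 3, hM4Di 2 or hM4Di 3 it called 0. Vgf kept the call only without rM3Ds 1 or rM3Ds 2 and otherwise lay at adjusted p of 0.0512 to 0.16, and Nr4a2 kept it only without rM3Ds 1, with 0.0752 to 0.3 otherwise.

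The 2 genes called for rM3Ds were both among the 103 higher genes of hM3Dq. The 2 comparisons share the EGFP libraries, so their lists are not independent. Across all 13584 genes the fold changes of hM3Dq and rM3Ds had r = 0.068 and a covariance of 0.0133, against 0.5 and 0.0614 in 50 simulations of unchanged groups set against the same EGFP libraries. For hM3Dq and hM4Di these were 0.647 and 0.1377 against 0.505 and 0.0613, and for rM3Ds and hM4Di 0.108 and 0.0156 against 0.502 and 0.0611. Genes are not independent replicates, the 3 EGFP libraries could not be split, and part of any excess may come from them. The simulations drew each gene on its own and so lack the shared shift of EGFP 1, rM3Ds 2 and rM3Ds 3. They therefore cannot show whether the real values differ from those of unchanged groups with that shift. Without the 3 libraries that stand apart r was 0.379, 0.414 and 0.316. No simulation was run for that setting, and the simulated values above are no reference for it. Of the 107 genes 43 were also called against both other receptors, 42 of them higher, led by Fosl1, Atf3, Clcf1, Ptgs2 and the fibronectin receptor subunit Itga5.

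Whether the response to hM3Dq lasted was asked 3 days after the stimulation. The genes that hM3Dq raised at 90 min had smaller fold changes at that time. Of the 103 genes that were higher at 90 min 95 were tested at 3 days, and their median log2 fold change was -0.04 against 1.07 at 90 min, with 46 of them above 0. At an unadjusted p under 0.05 in edgeR 12 of them were higher and 9 lower at 3 days, and without mCherry 3 edgeR called 9 higher and 9 lower of 96. They were selected by their 90-min values, which favours larger values at that time. Fos was at 10.7 ± 0.54 CPM with hM3Dq and 14.7 ± 1.6 CPM with mCherry (-0.47 ± 0.12, adjusted p = 0.262, n = 3 per group). Nr4a1 was at 14.3 ± 0.62 and 7.24 ± 1.27 CPM (0.98 ± 0.15, adjusted p = 0.199) and Nr4a3 at 2.37 ± 0.18 and 0.69 ± 0.18 CPM (1.76 ± 0.25, 0.199). Egr3, an immediate-early transcription factor, had 0 counts in each hM3Dq library and 4.05 ± 1.00 CPM with mCherry, which is at least 25-fold lower with a floor of 3 counts per library (adjusted p = 0.126). Whether an exact 0 in all 3 libraries is an absence or an effect of the quantification was not tested, and the bound holds only for an absence. Igfbp3, an IGF-binding protein, was at 232 ± 33.1 and 423 ± 8.73 CPM (-0.86 ± 0.12), Amy1 at -1.15 ± 0.15 and Igflr1 at -1.22 ± 0.16 (0.199 for each). Egr1 was at -0.56 ± 0.43, Chrm3 at 0.25 ± 0.12 and Gfap at 0.68 ± 0.23, and none of the genes named here passed over all genes.

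At 3 days edgeR called 0 of 12807 genes, with 583 higher and 957 lower at an unadjusted p under 0.05. DESeq2 called 156, of which 73 were higher, and limma-voom called 1. The library mCherry 3 decided this count: without it edgeR called 1257 genes, 536 higher and 721 lower, and without hM3Dq 2 it called 1. Without mCherry 3 the spread left was small. The chi-square per degree of freedom between the counts of mCherry 1 and 2 was 4.58, and within hM3Dq it was 2.66 to 6.32. For pairs with mCherry 3 it was 61.69 and 61.33. The labels do not say that replicates are separate cultures, so the 1257 calls may rest on a partly technical spread. With offsets for GC content and transcript length, chosen after seeing the data, edgeR called 449 with all 6 libraries. Both alternatives called 411 genes, all in the same direction, 202 higher and 209 lower. The 2 fits share 5 of the 6 libraries, so this overlap is no independent check of these genes. Groups did not overlap in 25.1% of genes, against 10% by chance. Genes are not independent replicates, so this share can lie far from 10% without an effect of the receptor.

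The genes called by both alternatives at 3 days included list members, which were chosen after their values were seen and are given with the offset fit. Among 29 immediate-early genes 3 were higher, Nr4a1 (0.91 ± 0.12), Nr4a3 (1.85 ± 0.25) and Fosl2 (0.39 ± 0.06), and 3 were lower, Egr3, Egr2 (-0.94 ± 0.22) and Fos (-0.57 ± 0.09). Among 34 reactive astrocyte genes 5 were higher, Steap4 (0.76 ± 0.09), the oncostatin M receptor gene Osmr (0.62 ± 0.09), S1pr3, Fbln5 and Ptx3, and Clcf1 was lower (-0.63 ± 0.09). Homeostatic astrocyte genes had 4 of 21 higher, among them the water channel Aqp4 (0.43 ± 0.10), Clu and Aldoc. Glycolysis genes had 4 of 25 higher, Pfkl, Tpi1, Hk2 and Eno1, at 0.37, 0.31, 0.39 and 0.27. Matrix genes had 4 of 27 higher, the collagen cross-linking enzyme Lox (0.67 ± 0.09), Adamts4, Adamts9 and Col6a1. Growth factors had 2 higher, Cntf (0.51 ± 0.07) and Inhba (0.45 ± 0.06), and 4 lower, Clcf1, Pdgfb, Nrg1 and Bmp4. No cell cycle, cholesterol or cell type marker gene was called by both. Without mCherry 3, however, 6 cholesterol genes were called lower and 1 higher, and 2 fibroblast and mural cell markers higher and 1 lower. Both alternatives called 411 genes in all, with 12807 tested, so a short list without a call says little.

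With all libraries and no offsets, camera placed 7 lists apart at 3 days. Reactive astrocyte genes had a median of 0.23, with 9 of 34 higher and 1 lower when adjusted over the list alone (adjusted p = 2.54e-05), glycolysis genes of 0.22 (0.000117), cAMP-CREB responsive genes of 0.29 with 3 of 23 higher when adjusted over the list alone (0.000747), unfolded protein response genes of 0.12 (0.00747), homeostatic astrocyte genes of 0.12 (0.0153) and heat shock genes of 0.17 (0.0206). Cell cycle genes had a median of -0.39 (0.0024). With an estimated correlation their adjusted p = 0.29, 0.448, 0.312, 0.448, 0.312, 0.312 and 0.625 in that order, so none passed. The cell cycle list lost the camera call without mCherry 2 or mCherry 3 (0.118 and 0.11). The unfolded protein response list lost it with the offsets for GC content and transcript length (median 0.09, camera adjusted p = 0.147). Immediate-early genes had a median of 0.11 and, with Egr3 at its bound, a mean of -0.04 (camera adjusted p = 0.413).

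**Figure D3:**
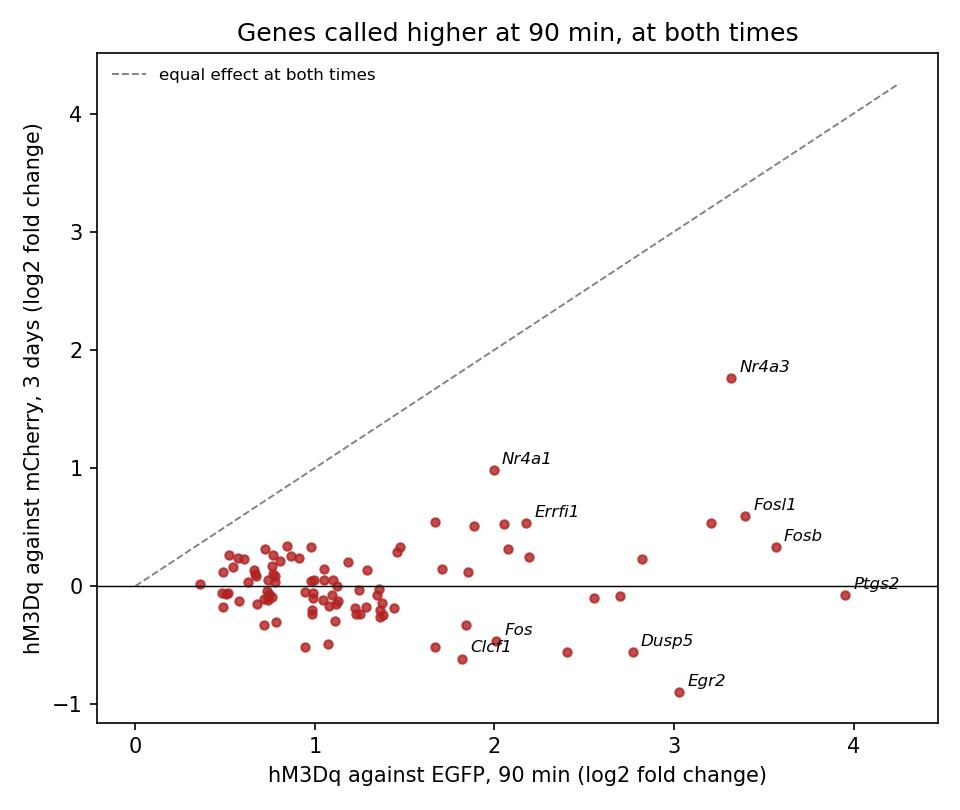
Log2 fold change of hM3Dq against its control at 90 min (x axis) and at 3 days (y axis) for the 95 genes called higher at 90 min and tested at both times. All 95 lie below the dashed line of equal effect, with medians of 1.07 at 90 min and -0.04 at 3 days.

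The test of the difference between times asked which hM3Dq effects changed, each taken against its own control. The effect on Arc, a synaptic immediate-early gene, was lower at 3 days than at 90 min by 4.25 (log2 difference -4.25 ± 0.56), that on Ptgs2 by 4.02 (-4.02 ± 0.31), that on Egr2 by 3.92 (-3.92 ± 0.29) and that on Dusp5 by 3.32 (-3.32 ± 0.25). For Egr3 the difference was at most -7.92 with the floor of 3 counts per library, from 3.28 at 90 min to a bound of -4.64 at 3 days, with the same doubt about its counts of 0. The effects on Rhobtb2 and Nuak1, a kinase related to AMPK, were higher at 3 days by 0.90 ± 0.16 and 0.64 ± 0.12. Rhobtb2 went from -0.49 to 0.40 and Nuak1 from -0.69 to -0.05, none of which passed within its time, and with the replicate block both differences lost their calls (adjusted p = 0.0564 and 0.0736). Of 32 immediate-early genes 12 differed over all genes, all with a lower signed log2 fold change at 3 days, and 23 when adjusted over the list alone (camera adjusted p = 2.45e-36, and 0.00217 with an estimated correlation). The calcineurin-NFAT, growth factor, ERK feedback and cAMP-CREB lists also differed by camera with both correlations (adjusted p = 0.00447, 0.00217, 0.0113 and 0.0434 with an estimated correlation). The inflammatory, cholesterol and synapse-regulating lists differed with the preset correlation only (adjusted p = 0.0654, 0.223 and 0.0654 with an estimated correlation). Of 13391 genes edgeR called 53, of which 51 had a lower and 2 a higher signed log2 fold change at 3 days than at 90 min.

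The control plasmid also differs between the times, and whether both times came from 1 experiment is not given by the labels. The controls differed in level for some named genes, with CPM normalised within each time. Nr4a1 was at 117 CPM with EGFP and 7.20 CPM with mCherry, Atf3 at 7.73 and 0.70 and Fosl1 at 3.93 and 0.63. Fos, at 13.4 and 14.7, and Ptgs2, at 8.65 and 9.70, lay close. Egr2 was higher with mCherry, at 2.70 and 6.37. What this does to the fold changes was not tested. The count of 53 was 202 with DESeq2 (31 higher, 171 lower), 170 without EGFP 1 (31 higher, 139 lower), 501 without EGFP 1 and mCherry 3, chosen after seeing the data (160 higher, 341 lower), and 28 to 33 without hM3Dq 1 or 2 at 90 min or hM3Dq 1, 2 or 3 at 3 days. Rhobtb2 lost its call without any of 7 of the 12 libraries (adjusted p = 0.0643 to 0.128) and Nuak1 without any of 10 (0.0572 to 0.156).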

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

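The tests of a swap, of fibroblast and mural markers, of GC content, length and depth for mCherry 3, and of hM4Di 1 left out were chosen after the result was seen.

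The effect of hM3Dq differed between 90 min and 3 days for 16 named genes by a test of the difference itself, each taken against its own control (edgeR adjusted p from 3.55e-05 to 0.0368). The controls of the 2 times differed in level for some of these genes, as given above. Arc, Egr2, Rhobtb2 and Nuak1 were named for hM3Dq only because this same test called them. Most of the others were named because they were called at 90 min. The count of 16 therefore follows in part from how the genes were chosen. Nr4a1 and Nr4a3, also named for hM3Dq, were not among the 16. The log2 difference, 3 days less 90 min, was -2.43 for Clcf1, -3.32 for Dusp5, -3.92 for Egr2, -4.02 for Ptgs2, -3.23 for Fosb and -2.47 for Fos. It was -2.66 for Nr4a2, -2.79 for Fosl1, -1.62 for Dusp10, -4.25 for Arc, -2.59 for Atf3, -1.16 for Inhba and -4.41 for Egr4, whose counts with EGFP and at 3 days lay near the floor of 3 counts, so that its difference is uncertain. Rhobtb2 and Nuak1 were at 0.90 and 0.64. For Egr3 the difference was at most -7.92, a bound, since its counts were 0 in the 3 libraries of hM3Dq at 3 days, and whether these are an effect of the quantification was not tested. Of 100 splits of the 12 libraries, drawn with the real one included, 2 gave at least the 53 called genes of the real one, a share under 0.05. The other was the real grouping with hM3Dq and mCherry exchanged at 3 days, with 75 called genes. The other drawn splits that kept the real grouping at 90 min gave 29 to 41, and those that did not gave 0 to 2. The count therefore follows the grouping at 90 min, and the share does not test the difference between times.

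EGFP 1, rM3Ds 2 and rM3Ds 3 stood apart from the other 9 libraries at 90 min, and the shifts within EGFP and within rM3Ds had r = 0.764 across genes. GC content and transcript length accounted for an R2 of 0.00257 of this shift, which argues against such a bias. A swap of EGFP 1 and rM3Ds 1 was tested on Vgf, which lay 3.39 higher (log2 CPM) in rM3Ds 1 than in EGFP 2 and 3, and at -3.68 in EGFP 1 relative to rM3Ds 2 and 3. This argues against a swap but does not exclude it, since Vgf had the smallest p for rM3Ds under the present labels. More fibroblast and mural cells cannot be told apart from other causes, because the markers moved both ways, with a median of 0.52 and 6 of 11 above 0. A different culture or batch stays open as well, was not tested and is not given by the labels, and no biological explanation was tested.

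mCherry 3 stood apart from the other 5 libraries at 3 days. GC content and transcript length accounted for an R2 of 0.52 of its shift across genes (r = -0.594 with GC content and 0.516 with length), which is in line with a bias of library preparation or RNA quality that may explain part of it. Its depth of 17.6 M counts lay within the 16.6 to 19.7 M of the other libraries, which argues against lower depth. Its shift had r = 0.034 with that of the 3 libraries at 90 min over 12726 genes. A difference of the culture stays open, and no biological explanation was tested.

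Interferon-stimulated genes were higher with hM4Di against EGFP at 90 min, with a median log2 fold change of 0.71. After removal of the trend with GC content and length the median was 0.69, which argues against that bias. Without hM4Di 1 the median was 0.28, with 24 of 26 members above 0, so that library held a large part of the change. An effect of the receptor and a state of hM4Di 1 cannot be told apart for these genes, since only 3 libraries carry the receptor and adjusted p = 0.235 with an estimated correlation in camera. Both may contribute.

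For groups of 3 against 3 the 10 splits are too few for a share under 0.05. For hM3Dq against EGFP 1 of 10 splits, the real one, gave as many called genes (107 against 0 at most in the others, including those that part all 3 numbered pairs), and likewise for hM3Dq against rM3Ds (91 against 0) and against hM4Di (109 against 0). For rM3Ds against EGFP 2 of 10 splits gave as many, the real one with 2 and EGFP 1 with rM3Ds 2 and 3 against the rest with 3145, which points to the structure of the samples given above. For rM3Ds against hM4Di 2 of 10 did, with 2 in the real one and 123 for hM4Di 1 with rM3Ds 2 and 3 against the rest, again a structure of the samples. For hM4Di against EGFP all 10 did (0 in the real one, 0 at most in the others), and for 3 days all 10 did (0 against 2).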

How the results depend on the processing

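The removal of or a term for the 3 libraries that stand apart at 90 min, the removal of EGFP 1 with mCherry 3, the fit of only the 2 groups compared with the replicate block, and the GC content and length offsets were chosen after the data were seen. Single named genes, whether called or not, kept direction in 1009 fits, and also the side of the threshold where an adjusted p was given. They passed only under the alternative in 35, no longer passed in 175 and turned direction in 19. Lists called with all libraries kept both in 342, no longer passed in 84 and turned direction in 7 by the test. Other lists could only gain a call, and the lists called for rM3Ds were 15 with a term for the libraries that stand apart and for hM3Dq 15 without them. Counts stayed within 1.5 times in 105 and moved further in 69. DESeq2's size factors and the stricter filter moved no count of called genes further, and no filter moved only that at 3 days, from 0 to 1. Where a library was left out, fewer libraries were tested. For other changes the cause was not tested. The alternative without mitochondrial transcripts was not run, since no such gene was tested. With sequencing depth of 16.1 to 25.2 M counts, Egr3, with 0 counts in a whole group, is given as a bound, and the values of other genes near the floor of 3 counts, such as Egr4, are uncertain.

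Called genes moved as follows. For hM3Dq against EGFP the 107 became 232 with DESeq2, 66 with the replicate block, 28 with only the 2 groups compared and the replicate block, 206 with a term for the libraries that stand apart, and 50 to 103 with single libraries left out. For rM3Ds the 2 became 56 with DESeq2, 4 with the replicate block, 0 with only the 2 groups compared, 0 without the libraries that stand apart and 2 to 115 with single libraries left out. For hM4Di the 0 became 35 with DESeq2 and stayed 0 with single libraries left out. At 3 days the 0 became 156 with DESeq2, 1 with limma-voom, 449 with the offsets and 0 to 1257 with single libraries left out. For hM3Dq against rM3Ds the 91 became 463, 138 with only the 2 groups compared, 53 with the replicate block, 25 without the libraries that stand apart and 28 to 590 with single libraries left out. For hM3Dq against hM4Di the 109 became 420, 61 with the replicate block, 300 without and 383 with a term for the libraries that stand apart, and 38 to 106 with single libraries left out. None of the libraries that stand apart is in that comparison. For rM3Ds against hM4Di the 2 became 205, 0 with only the 2 groups compared, 0 with the replicate block, 0 without and 1 with a term for the libraries that stand apart, and 0 to 392 with single libraries left out. For the difference between times the 53 became 202 with DESeq2, 36 with the replicate block, all lower, 501 without EGFP 1 and mCherry 3, and 28 to 170 with single libraries left out. Only hM3Dq and EGFP have numbers that passed the check for pairing, which does not show that the numbers mark shared cultures. There the replicate block left 13 lists called, as without it, and among the genes named by rule it ended the calls of Gpr146, Mtss1, Mmp11 and Pik3ip1 and of no other. With only the 2 groups compared and the replicate block Egr1, Vgf, Nr4a3, Nfatc2 and Inhba lost theirs too. At 3 days every library correlated best with its own number, with r of 0.022 to 0.041, and the replicate block left 0 called.

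With an estimated correlation in camera the lists called fell from 13 to 7 for hM3Dq, 13 to 6 for rM3Ds, 7 to 0 for hM4Di and 7 to 0 at 3 days. With fry they were 9, 5, 1 and 1. With single libraries left out they were 10 to 14, 10 to 14, 4 to 9 and 6 to 8. Genes called higher with both hM3Dq and rM3Ds fell from 2 to 1 at a mean log2 CPM of at least 3 and to 0 without the libraries that stand apart.

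Genes that turned direction had not passed. Cell cycle genes turned by the test of the list, and 3 more called lists turned in their median alone. Synapse-regulating factors with rM3Ds were at -0.03 without the libraries that stand apart, inflammatory genes with rM3Ds at -0.02 without rM3Ds 1, and matrix genes with hM3Dq at -0.04 and -0.01 without hM3Dq 1 or EGFP 3. Gfap with hM3Dq was at 0.21 without the libraries that stand apart and at -2.33 to 0.21 with single libraries left out. Gfap with rM3Ds was at 0.47 with limma-voom, 0.77 with the replicate block, 0.84 without the libraries that stand apart and -0.69 to 1.86 with single libraries left out. Gfap with hM4Di was at 1.73 without and 1.23 with a term for the libraries that stand apart, and at -1.81 to 1.75. Egr1 with rM3Ds was at -0.13 to 0.65 with single libraries left out, and with hM4Di Nr4a1 was at 0.00 to 0.32 and Chrm3 at -0.26 to 0.74. Without the libraries that stand apart Fos with hM4Di was at -0.02 and Chrm3 at -0.29, and with a term for them Chrm3 was at -0.15. The cell cycle list with hM3Dq had a median of 0.21 without and 0.11 with a term for them, and -1.84 to 0.22 with single libraries left out. With rM3Ds it was at -0.08, -0.42 and -0.37 to 1.75.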

Other observations

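Genes named here were chosen after their values were seen. Of the 107 genes called for hM3Dq at 90 min 59 were in no list, 55 of them higher. Sgk1, a kinase induced by glucocorticoids and cell stress, rose from 35.4 ± 3.34 to 208 ± 11.4 CPM (log2 fold change 2.56 ± 0.20, edgeR adjusted p = 7.06e-05, n = 3 per group). Itga5, the fibronectin receptor subunit, rose by 1.36 ± 0.10, Ifrd1, a transcriptional co-regulator, by 1.12 ± 0.09, and Homer1, a scaffold of glutamate receptor signalling, by 1.13 ± 0.18. The oxidative stress genes Srxn1 and Hmox1 rose by 1.24 ± 0.12 and 1.10 ± 0.20. P2ry2, a purinergic receptor that couples to Gq, rose by 0.72 ± 0.12.

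Some genes outside the lists were called by edgeR at 3 days both with the offsets and without mCherry 3, and no test of them as a group was made. With the offsets Lrg1 and Hp, secreted acute-phase proteins, were at 1.14 ± 0.25 and 0.88 ± 0.21, and Bcl3, a regulator of NF-kB, at 0.77 ± 0.15. The binding proteins Igfbp4 and Igfbp3 moved in opposite directions, at 0.77 ± 0.11 and -0.95 ± 0.11.

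Besides Egr3, Gvin1 had 0 counts in each mCherry library at 3 days and 20.8 to 78 counts in hM3Dq, with the same doubt about the 0. The pseudogene Rpl14-ps1 had 0 counts in each hM4Di library at 90 min and 47.9 to 206 counts in hM3Dq. Reads of this pseudogene and its parent gene share sequence, so its counts are uncertain.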
